A study of Macaca fascicularis with 24 samples.

How the data were processed

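Brain punches of 8 cynomolgus macaques (Macaca fascicularis) were profiled by RNA sequencing, with 4 animals treated with a divalent siRNA against the Huntingtin gene and 4 left untreated. Each animal gave 3 punches, and each punch was 1 library, for 24 libraries in all. Per the labels' protocols, the punches were flash frozen, RNA was isolated on columns with a DNase step, and polyadenylated RNA was made into stranded libraries. The deposited values are raw read counts per gene, 1 file per library, with 29324 Ensembl gene IDs in each. Per the submitters' processing notes, STAR 2.5.3a and HTSeq 0.10.0 were used. The genome build and the annotation are not given in the sources used here. No entry without a gene was present, so all counted reads entered the totals. No molecular identifiers are named in the labels, so the intervals given for shares of reads cover counting error only.

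The files do not pair the gene IDs with names. The gene name table at hand has 40596 entries of the assembly T2T-MFA8v1.1, 0 of which carry an Ensembl ID, and 0 of the 29324 IDs matched it. The Huntingtin transcript, the 35 gene lists chosen before the data were examined, a search for seed matches of the siRNA and a fit without mitochondrially encoded genes were therefore not analysed here, and the level of the targeted gene was not used to check the treatment labels. The rule for naming genes, set before the data were examined, asked for a symbol, an adjusted p under the threshold, a mean of at least 1 CPM (reads of a gene scaled to a fixed library total) and no overlap between the groups, and took the largest changes in each direction. It was applied without the symbol, and at most 2 IDs per direction are printed. This limit departs from the rule, which allowed more genes per direction. Changed genes beyond the limit are described without an ID, although some genes with a printed ID had a larger adjusted p.

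Groups and animals were taken from the labels. The animal was the replicate: the counts of its 3 punches were summed, since the series description states that punches were sequenced separately and combined. Genes were kept with the filterByExpr rule of edgeR (minimum count 10), library sizes were scaled by TMM, and treated animals were compared with non-treated animals by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3). The Benjamini-Hochberg adjusted p had to lie under 0.05, with no minimum fold. Levels are CPM after TMM scaling, as mean ± SD over animals. Exact two-sided permutation tests over the 70 assignments of 8 animals were run on values per animal, and the smallest p they can give is 0.0286. Fits left with groups of unequal size used all assignments of the remaining animals. Groups without overlap then need not give the smallest p. Punch numbers were compared within animals over all 24 libraries with a quasi-likelihood F-test with animal as a term, and a further model tested whether the treatment effect differed between punch numbers.

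Abundant genes were defined as those that each held over 1% of all counted reads, which 12 genes did. This definition, the share of reads in these genes, and the fits without single libraries, without the 12 genes or with library size alone were chosen after the data were seen. All 276 pairs of libraries were compared by a chi-square test over genes with at least 20 reads in the pair, and no pair was close enough to be the same library deposited again. The smallest chi-square per degree of freedom was 3.92.

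The tests were tried on simulated counts drawn from the means and library sizes of the real data. For treated against non-treated animals, with 14892 genes, edgeR recovered 59% of 100 genes changed 2-fold and 88% of 100 genes changed 4-fold, with 12 false calls. DESeq2 recovered 70% and 89% with 39 false calls, and limma-voom 57% and 86% with 11. Over 14265 genes, the test of punch numbers recovered 89% and 98% with 10 false calls, and the test of a treatment effect that differs between punch numbers 51% and 85% with 6. All these shares may overstate recovery in the real data. The 2-fold and 4-fold genes were changed together, which loosens the adjusted threshold, and the spread of each gene was edgeR's own estimate. Where few genes pass, as with the 5 called between the real groups, the threshold is stricter.

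Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter of at least 1 CPM in 4 animals, punches scaled to equal depth, single punch numbers, the 24 libraries with a within-animal correlation, the replicate number as a block, 1 surrogate variable (sva 3.50.0), another threshold, and each animal left out. Adjusted p-values that DESeq2 gave as missing, for 1163 genes, were kept as missing. The real grouping was set beside all 35 splits of the animals into 4 and 4, and the punch numbers beside renumberings within animals, 100 in all with the real one.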

Results

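The data are 24 brain punch libraries from 8 cynomolgus macaques, a monkey used as a large-brained model for drugs given to the brain. The treatment was a divalent siRNA, a pair of linked small interfering RNAs that direct the cell's silencing machinery to a chosen transcript, here that of Huntingtin, the gene mutated in Huntington's disease. There were 4 treated and 4 non-treated animals, with 3 punches from each. The labels do not say which part of the brain a punch came from. Libraries held 6761946 to 15741415 counted reads, and the sum over the punches of an animal was 30822287 to 36878649. Libraries of the same animal were the most alike, with a median Pearson r of 0.979 across genes, against 0.966 between animals of the same group and 0.964 between groups. Genes are not independent replicates, so these correlations are descriptive.

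One library stood apart from the others. Punch 3 of non-treated animal 1 had reads in 11412 genes, where the other 23 libraries had 15946 to 17568. In this library the 12 most abundant genes held 78.4% of 8271894 reads (95% Wilson interval 78.4% to 78.5%). Its median r with the other libraries was 0.838. Punch 1 of treated animal 1 followed with 56.4% of its 14397505 reads in the 12 genes (95% Wilson interval 56.3% to 56.4%).

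**Figure D1:**
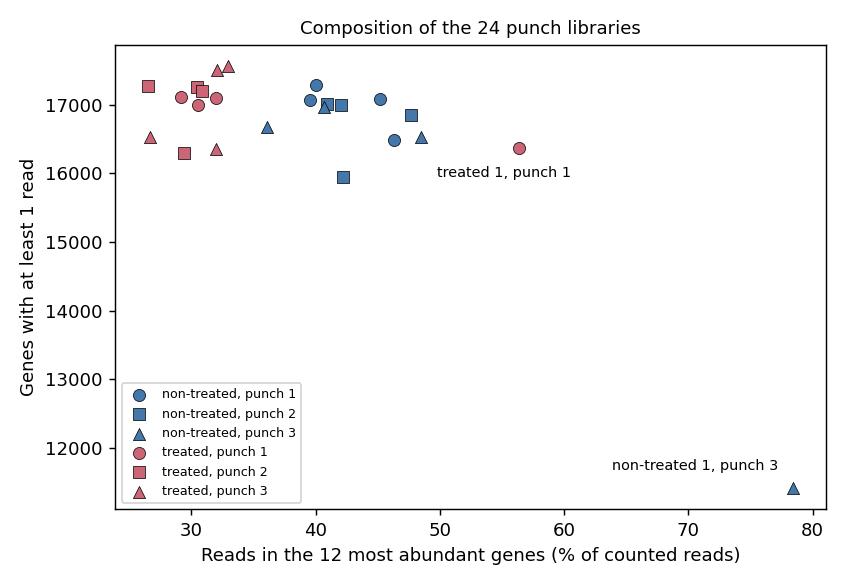
Genes with at least 1 read against the share of counted reads in the 12 most abundant genes (percent), 1 point per punch library, coloured by group and shaped by punch number. Punch 3 of non-treated animal 1 lies alone at 78.4% and 11412 genes, and punch 1 of treated animal 1 is the only treated library above 32.98%.

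The main comparison asked which transcripts differed in the brain after the siRNA. The groups are labelled only treated and non-treated, with no control siRNA or vehicle named, so silencing cannot be told apart from the dosing itself. Of 14892 genes tested, 5 changed, 1 higher and 4 lower in treated animals. The firmest change was in ENSMFAG00000036776, which fell from 17.2 ± 0.552 CPM in non-treated animals to 4.08 ± 0.613 CPM in treated animals (SD, n = 4 each), 76.3% lower. All 4 treated animals, at 3.36 to 4.66 CPM, lay below all 4 non-treated animals, at 16.6 to 17.9 CPM. Its log2 fold change was -2.08 (SE 0.147, edgeR quasi-likelihood adjusted p = 0.000173), and it was past the threshold whichever animal was left out. The separation held in single punches as well, with 12 to 22 CPM over the 12 non-treated libraries and 1.87 to 5.67 CPM over the 12 treated libraries. This is no separate support, since the gene was picked from the sums of these libraries and punches of 1 animal are not independent. In punch 3 alone, which holds the library with few genes of non-treated animal 1, the log2 fold change was -2.15 but the edgeR adjusted p was 0.277. Over the alternatives of all tools the adjusted p ran from 8.28e-39 with DESeq2 to this 0.277. The files do not pair the IDs with names, so none of these genes is named, and the level of the targeted transcript was not analysed here.

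The other 4 changes were less firm. ENSMFAG00000030190 fell from 5.59 ± 1.45 to 1.30 ± 0.425 CPM (SD, n = 4 each), a log2 fold change of -2.10 (SE 0.295, edgeR adjusted p = 0.0439). ENSMFAG00000037799, the only gene that rose, went from 0.584 ± 0.28 to 3.82 ± 1.17 CPM, 6.55-fold, with a log2 fold change of 2.71 (SE 0.372, edgeR adjusted p = 0.0433). It was counted with only 9 to 173 reads per animal. Of the remaining pair, one fell from 46.0 ± 6.93 to 14.2 ± 4.81 CPM (log2 fold change -1.70, SE 0.214, edgeR adjusted p = 0.0259), and the other, one of the 12 most abundant genes, fell from 21300 ± 4060 to 7330 ± 1500 CPM (log2 fold change -1.54, SE 0.186, edgeR adjusted p = 0.0244). None of these 4 stayed past the threshold through every fit that left out 1 animal. Their largest edgeR adjusted p over the alternatives lay between 0.702 and 0.895, in each case in punch 3 alone. That fit holds the library with few genes and was not repeated without it. In each of the 5 genes the groups did not overlap, and the exact two-sided permutation p was 0.0286, the smallest that 8 animals allow. This is no separate support, as the 5 were picked for their difference between the same animals.

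**Figure D2:**
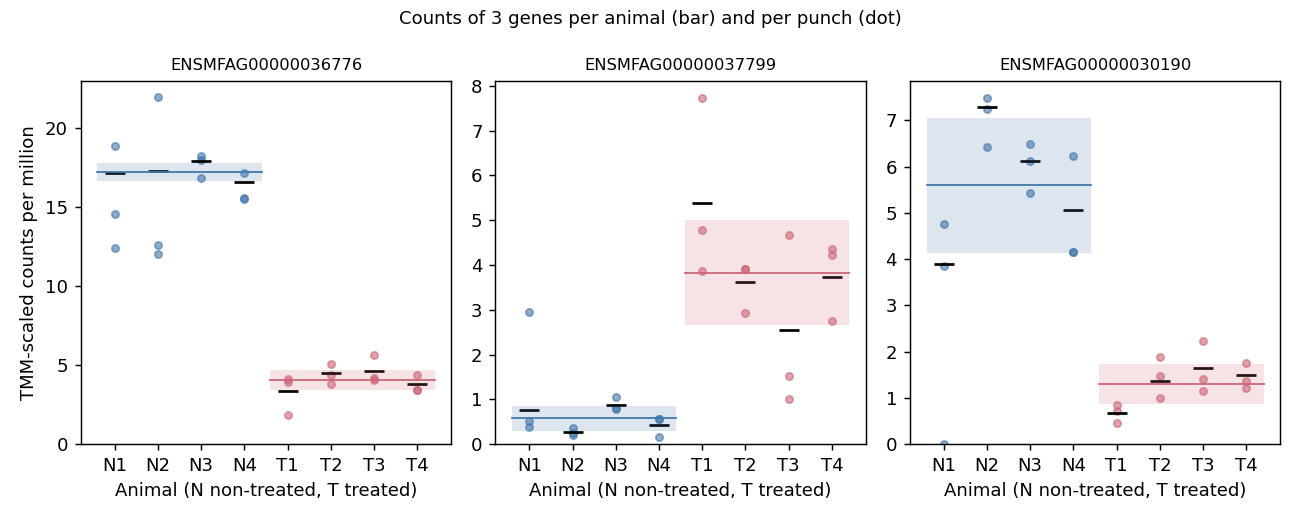
TMM-scaled read counts (CPM) of 3 changed genes in non-treated (N) and treated (T) animals, with a dot per punch, a black bar per animal, and the group mean with a band of 1 SD over the 4 animals. ENSMFAG00000036776 lies at 12 to 22 CPM in the non-treated punches and at 1.87 to 5.67 CPM in the treated punches.

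In most tested genes the 95% interval left room only for a change under 2-fold between the groups. For 11721 genes (78.7% of those tested) the 95% interval of the fold change lay within 2-fold in either direction, and for 14489 (97.3%) within 4-fold. These intervals are not adjusted for the number of genes. Smaller changes are not excluded, nor is a 2-fold change in the other genes. The common biological coefficient of variation between animals was 22.1%. At an unadjusted p under 0.05 there were 1439 genes, 635 higher and 804 lower, where chance gives 745, and the groups did not overlap in 791 genes (5.31%, where chance gives 2.86%). Neither excess was particular to the treatment grouping, since 3 other splits of the same animals into 4 and 4 gave more genes by each measure, up to 1963 and 1095. The number of changed genes depended on the tool and on single animals. DESeq2 called 158 genes, 51 higher and 107 lower, with the 5 edgeR genes among them. Without treated animal 1 edgeR called 43 genes, without treated animal 4 it called 11, without non-treated animal 2 it called 2, and without each other animal 1.

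**Figure D3:**
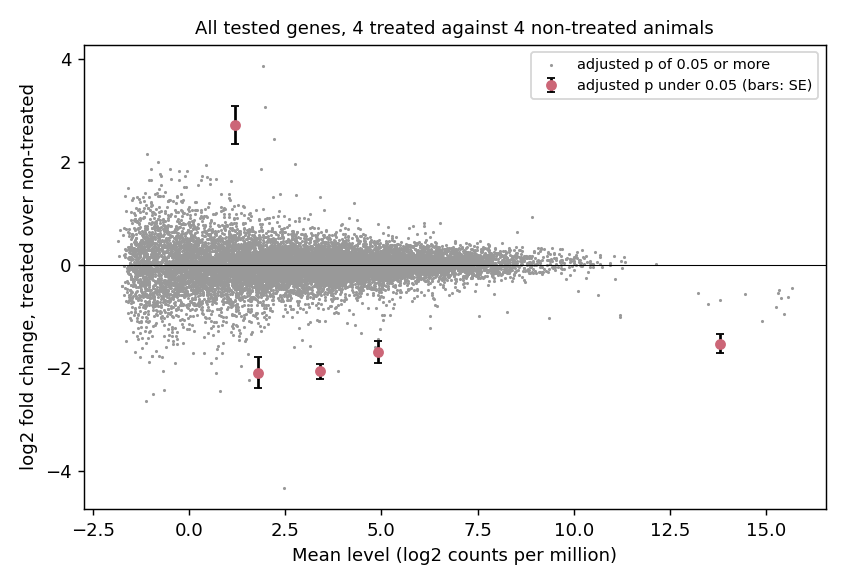
Log2 fold change (treated over non-treated) against mean level (log2 CPM) for 14892 genes, with the 5 genes past the edgeR threshold as large points with bars of 1 SE. The 12 most abundant genes, at the right end, all lie below 0.

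The most abundant transcripts made up a smaller part of the treated libraries. The 12 genes that each held over 1% of all reads took 44.7 ± 5.36% of the reads in non-treated animals and 33.0 ± 5.87% in treated animals (SD, n = 4 each), a difference of -11.7 percentage points that missed the threshold (exact two-sided permutation p = 0.0571). Treated animal 1 alone, at 41.5%, reached into the non-treated range of 39.5% to 52.0%, and without it the difference was -14.5 points. Without non-treated animal 2, at 39.5%, it was -13.4 points (exact permutation p = 0.0571). In both fits the groups no longer overlapped, which follows from which animal was left out. Without punch 3 of non-treated animal 1 it was -9.45 points, again with overlap (exact permutation p = 0.0571). Within punch numbers the difference was -13.9 points in punch 2 (exact permutation p = 0.0286). In punch 1 it was -5.75 points (exact permutation p = 0.514), and -12.2 without the library of treated animal 1, which at 56.4% lay above all 4 non-treated libraries of punch 1. In punch 3 it was -20.0 points, and -10.8 without the library of non-treated animal 1 (exact permutation p = 0.0286 for both). All 12 genes had a lower mean in treated animals under each of the 4 scalings tried, and 1 of them passed the edgeR test. Scaling by library size alone moved the median log2 fold change of all genes from -0.01 to 0.27, and 8 genes were then called, 6 higher and 2 lower, in place of 1 higher and 4 lower.

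Punch numbers were compared within animals to see whether they marked a difference shared between brains. Of 14265 genes tested, 153 differed between punch numbers (edgeR F-test), and 3124 had an unadjusted p under 0.05 where chance gives 713. Punches 2 and 3 both differed from punch 1, in 105 and 247 genes, mostly by less than 2-fold: the median size of the change among these was 0.46 and 0.42 on the log2 scale. The order of these counts was not stable, at 511 and 454 genes by limma-voom and 1580 and 1241 by edgeR without punch 3 of non-treated animal 1. Between punches 3 and 2, edgeR and limma-voom each called 0 genes, with 857 at an unadjusted p under 0.05 by edgeR. Without that library the count over all punch numbers rose to 1332 genes, which included all 153. With all libraries the count depended on single animals. It was 270 without non-treated animal 1, 129 without non-treated animal 4 and 221 without treated animal 4. However, it was 3 without non-treated animal 2, 1 without treated animal 1 and 0 without non-treated animal 3, treated animal 2 or treated animal 3. With punch 3 of non-treated animal 1 left out as well as 1 other animal, it ran from 4 to 1850. The lowest were 4 without non-treated animal 3 and 60 without treated animal 2.

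No gene had a treatment effect that differed detectably between punch numbers. By edgeR 0 of 14265 genes passed, as by limma-voom, with 283 at an unadjusted p under 0.05 where chance gives 713, and a smallest adjusted p of 0.508. In the 5 changed genes the unadjusted p of this difference was 0.177 to 0.616. On simulated counts of this design the test recovered 51% of genes whose effect differed 2-fold and 85% of those that differed 4-fold. These shares may be too high for the real data. Simulated libraries were drawn around the mean of their animal, which leaves out what set punch 3 of non-treated animal 1 apart, and the change lay in punch 2 alone. The 2-fold and 4-fold genes were also changed together, which loosens the adjusted threshold. Without punch 3 of non-treated animal 1 edgeR gave 497 real genes at an unadjusted p under 0.05, still fewer than chance gives. A count under the chance level is no evidence of equal effects, since the test may be too cautious on these data.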

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

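The tests of depth for the library with few genes, and of the abundant genes without 2 libraries and in punch 2 were chosen after the results were seen. Of 32 groups of 4 animals or libraries examined, 7 had a member far from the other 3, where chance gives about 1.6.

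In number of genes, the widest gap was in punch 3 of non-treated animal 1, with reads in 11412 genes where the other non-treated punch 3 libraries had 16525 to 16966. Lower depth is argued against, since a library of 6.76 M reads had 16527 genes and this one had 8.27 M. A few genes taking most of the counts is argued against as the whole account too: redrawn to the same number of reads outside the 12 most abundant genes, the other libraries kept at least 14640 genes, against 11400 here. A loss of RNA or of library complexity in this punch stays open and was not tested. No biological explanation was tested, since the labels set this punch apart in nothing.

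The abundant genes' share was 56.4% in punch 1 of treated animal 1, where the other treated punch 1 libraries had 29.2% to 32.0%. It was 26.7% in punch 3 of treated animal 2, where the others had 32.0% to 33.0%. The 2 libraries of largest share do not alone account for the smaller share in treated animals: punch 2, which holds neither punch 3 of non-treated animal 1 nor punch 1 of treated animal 1, differed by -13.9 percentage points with no overlap. Leaving out both libraries gave -12.1 points, which decides nothing, as they were picked by their shares. For depth, the change from the shallowest to the deepest punch of an animal had a median of -1.19 points. Its extremes, -38.9 and 24.4, came from the 2 animals that hold those libraries, and the other animals ran from -5.3 to 2.1. Animal totals overlapped, at 32.9 to 36.9 M reads in non-treated and 30.8 to 35.9 M in treated animals. Depth is thus argued against in the other animals and stays open in those 2. A difference in RNA handling between the groups stays open beside an effect of the treatment, and neither was tested.

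One gene among the 12 passed the edgeR test. Its log2 ratio to the other 11 differed by -0.848, treated minus non-treated, which decides nothing, as the gene was picked for its change. Over all 12 genes, with their mean taken out of each animal, differences ran from -0.757 to 0.312. An equal shift of all 12 is argued against, since the largest of these had an exact permutation p of 0.0286 that allows for the choice among 12, the smallest that 8 animals can give. The gene's name and function were not used here, and a treatment effect on it remains a hypothesis.

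Genes with a read also stood apart in punch 2 of non-treated animal 2 (15946, others 16846 to 17010), punch 1 of treated animal 1 (16371, others 16990 to 17109) and punch 2 of treated animal 1 (16302, others 17202 to 17268). One of the genes that fell was at 56.4 CPM in non-treated animal 2 and at 41.9 to 43.1 CPM in the other non-treated animals.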

How the results depend on the processing

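The fits without single libraries, without the abundant genes, with library size alone and all values for the share of reads were chosen after the data were seen. The cause was not tested unless stated. The log2 fold change of ENSMFAG00000036776 kept its side of the threshold in 25 of 26 alternatives, with a range of -2.15 to -1.79. The other 4 changed genes kept their direction but missed the threshold in 7, 10, 11 and 12 alternatives.

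The count of changed genes, 5 by edgeR, was 158 with DESeq2, 15 with no filter, 9 with at least 1 CPM in 4 animals, 3 with punches at equal depth, 74 with the 24 libraries and a within-animal correlation, 68 with punch number added, 1 in punch 1, 15 in punch 2, 0 in punch 3 (edgeR), 19 with 1 surrogate variable, 18 at the looser threshold, 21 without punch 3 of non-treated animal 1 and punch 1 of treated animal 1, 2 without the 12 abundant genes and 8 with library size alone. Leaving out each animal gave 1 to 43. Without the 12 genes the folds of the others hardly moved, while the adjusted p was 0.0538 in 2 genes.

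With the replicate number as a block, 2 genes were called. The numbers share no stated animal or batch, and the correlations of same-numbered animals were 0.00221, 0.0438, 0.253 and -0.128. Only number 3 correlated best with its own.

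Punch numbers, 153 genes, gave 298 with limma-voom, 289 with no filter, 1332 without punch 3 of non-treated animal 1, 1294 also without punch 1 of treated animal 1, and 0 to 270 when each animal was left out. Without that punch and 1 more animal it was 979 without non-treated animal 2, 4 without non-treated animal 3, 1620 without non-treated animal 4, and 877, 60, 346 and 1850 without treated animals 1 to 4. The treatment effect between punch numbers gave 4 genes with no filter, 1 without both libraries and 6 without that punch and treated animal 4, against 0.

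The share of reads, -11.7 points, passed the exact test as the mean of punch shares (-13.2), without both libraries (-12.1), in punch 2 (-13.9), in punch 3 (-20.0, or -10.8 without the library of non-treated animal 1) and in punch 1 without the library of treated animal 1 (-12.2). It missed the test in 9 of 16 alternatives: without punch 3 of non-treated animal 1 alone (-9.45), in punch 1 and in 7 of the 8 fits without an animal (exact p of 0.0571 to 0.114). Leaving out each animal gave -14.5 to -9.21. Fits without treated animal 1 or its punch 1 left out the largest treated share.

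RLE, upper-quartile and limma-voom counts of changed genes, and the count without punch 3 of non-treated animal 1, stayed within 1.5 times of 5. The planned results for Huntingtin, the gene lists, the seed matches and the fit without mitochondrially encoded genes were not run.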

Other observations

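The test of the changed genes without the abundant genes and the count of splits for unadjusted p-values were chosen after the results were seen. Some genes were present in some animals and nearly absent in others without following the treatment. In 12 genes every animal had either 50 or more reads or 2 or fewer, with animals of both kinds. One had 418 to 728 reads in 5 animals of both groups and at most 2 in the other 3. In 5 of the genes a single animal carried the reads, and for 3 of these it was treated animal 4. Their names were not used here, and no cause was tested.

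Other groupings of the animals were compared with the real one. Of the 35 splits into 4 and 4, only the real one gave as many as 5 edgeR calls (1 of 35), with 2 as the highest other count. This argues against chance for that count but does not exclude it, since 1 of 35 is the least these splits can give. For DESeq2 chance stays open: 3 of 35 splits, the real one included, gave as many as its 158 calls, up to 242. The other 2 exchanged non-treated animal 3 with treated animal 1 or treated animal 4. Chance also stays open for the 1439 genes at an unadjusted p under 0.05 and the 791 genes without overlap. As many of each were given by 4 of 35 splits, the real one included, and the highest other counts were 1963 and 1095. The 4 changed genes outside the abundant set kept at least 0.995 of their log2 fold change without the 12 abundant genes and the library with few genes. This decides nothing about the abundant genes, since leaving them out moved the log2 fold change of all genes by a median of only 0.000515.

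Among 100 numberings of the punches within animals, 1 gave as many as 153 genes, the real one, with 2 as the highest other count. Without punch 3 of non-treated animal 1 it was again 1 of 100, with 1332 genes against 4. Chance numbering is thereby argued against but not excluded, since 1 of 100 is the least these numberings can give. For the treatment effect between punch numbers all 35 splits gave at least the 0 genes of the real one, the highest other count being 1, so this count decides nothing.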
